A study of Mus musculus with 12 samples.

How the data were processed

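The series holds RNA sequencing of left ventricle from 12 mouse samples, 3 in each combination of genotype (wild type or T497A) and surgery (sham or TAC). The cell type label reads cardiomyocyte while the tissue label reads left ventricle, and the counts are treated here as those of ventricular tissue. The labels give 1 batch date for all samples, surgery at 10 weeks of age and tissue at 11 weeks. Per the labels, RNA was purified with RNeasy columns, libraries were made with the KAPA mRNA HyperPrep kit and sequenced on a NextSeq2000 with 50 cycles from a single end. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.4, aligned with STAR 2.7.3a, counted per gene with featureCounts (Subread 1.6.3) and tested with limma 3.50.3. These notes name both a mouse build (mm10) and a human one (GRCh38) without saying what each was used for. The deposited values are raw read counts per gene, as whole numbers in 12 columns, all of which were used. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so genes that overlap on opposite strands, and genes with near-identical copies such as Hba-a2, Eno1b, Ifi202b and pseudogenes, are uncertain.

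All 55401 gene IDs carry the mouse prefix. Names and coordinates came from GENCODE M21 on GRCm38, in which 54349 IDs matched with their version, 55141 without it and 260 not at all. Total counts ran from 58932759 to 72594085 per library. Between libraries of a group, the chi-square of the differences per degree of freedom was 11.4 to 153, so the spread between libraries exceeds counting error. Genes were filtered with filterByExpr, which left 17699, and libraries were scaled with TMM. Levels are CPM with TMM factors, as mean and SD of 3 libraries, and log2 CPM used a prior count of 2.

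Groups were taken from the labels alone, by the library name in each sample's description. Every sample title ends in the same replicate tag, and 2 of the 3 T497A sham columns of the counts table write the genotype without its first letter, so these columns were matched to their samples by genotype, surgery and number. The main test was the quasi-likelihood F test of edgeR 4.0.16 with robust estimation in R 4.3.3, with 1 mean for each of the 4 groups over all 12 libraries. The 5 planned comparisons were TAC against sham in each genotype, T497A against wild type after each surgery, and the interaction of genotype and surgery. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. Errors beside log2 fold changes are standard errors. An exact test of 3 against 3 cannot fall below 0.1, so single genes rest on this model.

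Before the data were examined, 33 gene lists (883 members) were written down, together with the comparisons, the main alternatives and the rule for naming genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Members were also counted among the genes called, with p adjusted over all genes and over the list alone. A score per library, the mean log2 CPM of a list, was tested for the interaction by exact permutation of genotype within each surgery (400 reassignments). Named are Prkca, 16 fixed genes, and in each comparison the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM and no overlap between the libraries of the groups (an overlap was allowed for the interaction), leaving out unnamed genes and pseudogenes. To these come up to 4 called members with the smallest p of each list described. The overlap of calls between the 2 genotypes was set against the product of the list sizes over the genes tested, and sizes of response were compared by a Deming slope with a jackknife over the libraries.

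The alternatives written down at that time were DESeq2 size factors, the DESeq2 1.42.0 test, limma-voom with quality weights, no filter, a stricter filter (1 CPM in 6 samples), robust estimation off, the replicate number as a block, mitochondrial, haemoglobin and rRNA genes removed, only the 2 groups compared, and each library left out in turn. Chosen after seeing the data were a fit without the T497A sham group, autosomal protein-coding genes only, library totals without TMM factors, and 4 further contrasts: surgery averaged over genotypes, genotype averaged over surgeries, T497A TAC against wild-type sham and wild-type TAC against T497A sham.

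The test was checked on counts simulated from these data with 200 genes changed in a single group. Fewer genes changed there than were called in the data, which makes the threshold on p stricter, so the shares that follow need not hold for the data. At 1.5, 2 and 4-fold, edgeR recovered 68.7, 80.6 and 100% in the TAC comparison in wild type (5.14% of its calls were false), and 65.7, 85.1 and 98.5% in that in T497A (4.05%). It recovered 74.6, 89.6 and 95.5% for genotype after sham (2.81%), 62.7, 79.1 and 98.5% for genotype after TAC (3.03%), and 28.4, 65.7 and 95.5% for the interaction (3.82%). For TAC in wild type, DESeq2 recovered 73.1, 88.1 and 100% with 16.3% false and limma-voom 58.2, 79.1 and 100% with 3.07% false. Sequence reads were not used here, so the mutation itself was not looked for, and neither splicing nor transcript isoforms were analysed here. Some genes that the naming rule selects are not reported here.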

Results

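Messenger RNA was sequenced from 12 mouse left ventricle samples that fall into 4 groups of 3. The mice were labelled wild type or T497A, a point mutant of Prkca in which a threonine of protein kinase C alpha that is normally phosphorylated is replaced by alanine. Each had undergone transverse aortic constriction (TAC), in which the aorta is tied against a 27-gauge needle so that the left ventricle pumps against a raised pressure, or a sham operation, at the age of 10 weeks. Tissue was taken 1 week later. The series concerns the removal of phosphorylation of this kinase in heart failure, and its design asks how the ventricle responds to pressure overload with and without the mutation. Total counts ran from 58932759 to 72594085 per library, and 17699 of 55401 genes passed the filter on low counts. Levels are given as normalised read counts (CPM). Pearson correlations of log2 CPM across genes were 0.980 to 0.990 between libraries of a group and 0.937 to 0.982 between groups. The labels number the libraries but do not say that each came from its own animal, so p-values measure only the spread between these libraries.

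Prkca (ENSMUSG00000050965.14, GRCm38 chromosome 11, 107933387 to 108343928, minus strand) was detected in every library. It stood at 47.4, 43.5 and 42.2 CPM in the wild-type sham libraries and at 35.7, 34.7 and 31.1 CPM in the T497A sham libraries. After TAC it stood at 49.2, 50.7 and 51.0 CPM in wild type and at 50.3, 44.7 and 43.7 CPM in T497A. In log2 units with the standard error, it was lower in T497A than in wild type after sham (-0.39 ± 0.07, adjusted p = 0.0056) and rose with TAC in T497A (0.45 ± 0.07, adjusted p = 0.00050). The rise in wild type was small (0.18 ± 0.07, adjusted p = 0.049) and lost its call in 11 of 22 alternatives, with adjusted p of 4.7e-05 to 0.17. It was lost without wild-type sham 2 (0.13) or 3 (0.17), T497A sham 2 (0.060), wild-type TAC 1 (0.076), 2 (0.085) or 3 (0.11), and T497A TAC 2 (0.082) or 3 (0.051). The T497A and wild-type TAC groups were not called apart for Prkca (-0.12 ± 0.07, adjusted p = 0.21), although they were without TMM scaling factors (-0.37, adjusted p = 0.0012; 0.0012 to 0.52 over its alternatives). A point mutation leaves no mark in counts per gene, so these levels do not check the genotype labels.

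Other transcripts bear on the labels, which do not give the sex of the mice. Xist (chromosome X, 103460366 to 103483254), the RNA that silences an X chromosome in females, stood at 184 ± 28.3 CPM (SD, n = 3) in the T497A sham group, against 0.65 ± 0.0907 in wild-type sham, 0.514 ± 0.203 in wild-type TAC and 0.461 ± 0.196 in T497A TAC. The Y-linked helicase gene Ddx3y (chromosome Y, 1260771 to 1286629) stood at 0.252 ± 0.148 CPM in T497A sham and at 105 ± 2.31, 80.1 ± 6.05 and 92.7 ± 2.87 CPM in these other groups. Both comparisons that use the T497A sham group, and the interaction, therefore also compare libraries with and without Y-linked transcripts. In addition, 104 autosomal transcripts differed at least 4-fold between the sham groups, 83 higher and 21 lower in T497A. After TAC the estimated difference between the genotypes had the opposite sign for 95 of them and the same sign for 9, and 72 were called, 71 with the opposite sign. On a linear scale from the wild-type sham level (0) to the T497A sham level (1), their median position was 0.685 in wild-type TAC (interquartile range 0.424 to 1.02) and 0.0321 in T497A TAC (-0.00718 to 0.123). Chromosome 11, which carries Prkca, held 33 of the 104 (31.7%, against 8.25% of the autosomal genes tested), and the next chromosome held 9. For these reasons group names are those of the labels throughout, and a direction by genotype is a direction between labels.

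**Figure D1:**
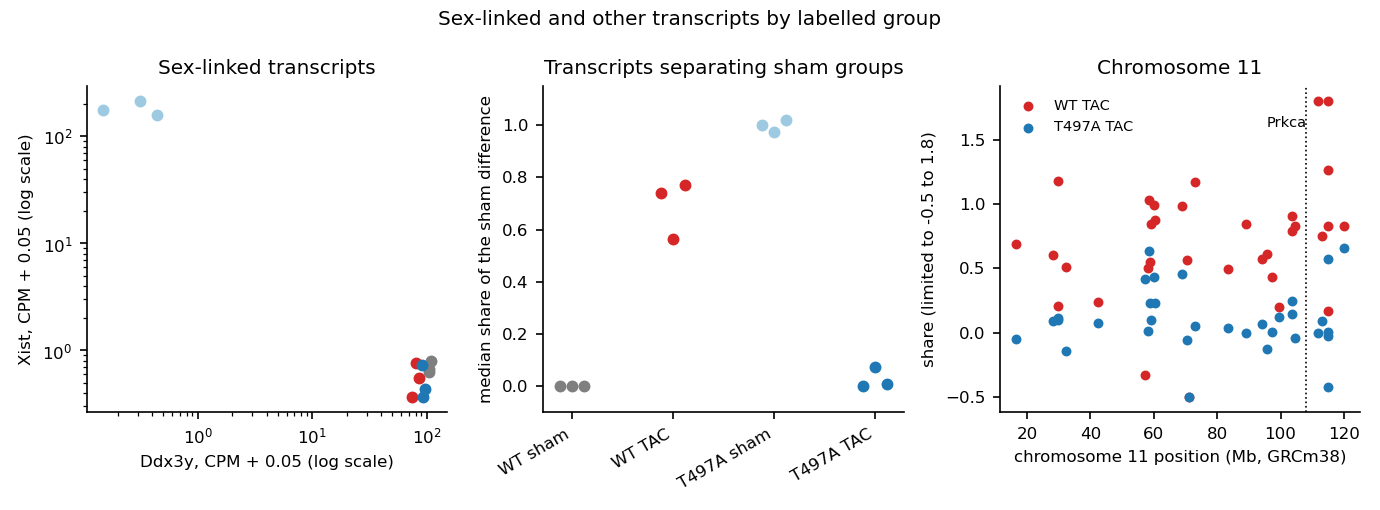
Left, Xist against Ddx3y in each of the 12 libraries (CPM + 0.05, log scales); centre, the median position of 104 autosomal transcripts per library between the wild-type sham (0) and T497A sham (1) levels; right, the positions of those on chromosome 11 by coordinate in Mb, limited to -0.5 to 1.8, with Prkca dotted. The T497A sham libraries stand apart for Xist and Ddx3y, and the wild-type TAC libraries lie at 0.562 to 0.772 in the centre panel, against 0.000816 to 0.0746 for T497A TAC.

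The response of the wild-type ventricle to pressure overload was a large rise of natriuretic peptide, fetal muscle and matrix transcripts with a fall of several calcium cycling genes and of mitochondrial transcripts. Nppa, the precursor of atrial natriuretic peptide, went from 88.4 ± 6.9 CPM after sham to 2596 ± 189 CPM after TAC (SD, n = 3; log2 fold change 4.88 ± 0.42, adjusted p = 1.4e-05). Nppb, the precursor of its ventricular relative, went from 125 ± 35.8 to 525 ± 66.4 CPM. Myh7, the slow myosin heavy chain of the fetal ventricle, rose (3.36 ± 0.51), as did skeletal actin Acta1 (3.16 ± 0.34) and the stretch-responsive cofactor Ankrd1 (1.70 ± 0.10). Col1a1 and Col3a1, the main fibrillar collagens, rose by 4.09 and 3.70 log2 units, and Postn, a matrix protein of activated fibroblasts, by 5.06. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell (-1.17 ± 0.10) together with its inhibitor Pln (-1.02 ± 0.11), the release channel Ryr2 (-0.70 ± 0.07), the adult myosin Myh6 (-1.12 ± 0.10) and Cpt1b, which admits fatty acids to mitochondria (-1.07 ± 0.12). Among the largest changes, the secreted matrix regulator Cthrc1 rose from 0.22 ± 0.141 to 66.7 ± 43.6 CPM, while Ppl fell (-3.61 ± 0.17).

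Gene lists fixed beforehand moved as groups in wild type. Of 49 matrix genes 48 rose and 0 fell (49 and 0 adjusted over the list alone; median 2.94), among them the basement membrane collagens Col4a1 (1.89 ± 0.10) and Col4a2 (1.73 ± 0.09) and the collagen VI chain Col6a3 (2.22 ± 0.12). Of 25 fetal programme genes 17 rose and 2 fell (18 and 2 adjusted over the list alone), including Tgfb2 (1.93 ± 0.13) and the calcineurin target Rcan1 (1.45 ± 0.11). In fatty acid oxidation 39 of 40 genes fell (39 adjusted over the list alone), with the thiolase Acaa2 (-2.05 ± 0.10) and Hadha (-1.45 ± 0.07) among them. All 54 respiratory chain genes encoded in the nucleus fell by both adjustments, as did 37 of 39 genes of the citrate cycle and branched-chain amino acid breakdown (37 adjusted over the list alone), where 2 rose. Of 13 mitochondrially encoded transcripts 11 fell (12 adjusted over the list alone), for example mt-Nd5 (-1.12 ± 0.15), and mitochondrial genes took 12.6 ± 2.63% of counts in wild-type TAC against 20.2 ± 0.979% in wild-type sham (SD, n = 3). The adjusted p of these 6 lists was 4.6e-22 to 4.8e-05 with a preset correlation between genes and 0.34 to 0.42 with an estimated correlation.

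Markers of proliferation, cell types and the adult muscle moved too. Of 33 cell cycle genes 32 rose and 1 fell (the same counts adjusted over the list alone), with the mitotic kinase Cdk1 at 3.08 ± 0.21. Macrophage markers rose for 14 of 20 and fell for 2 (14 and 3 adjusted over the list alone), including the lipid receptor Trem2 (3.00 ± 0.25) and the lysosomal protein Cd68 (1.51 ± 0.14). Fibroblast markers rose for 15 of 19 and fell for 2 (the same adjusted over the list alone). Of the adult sarcomere genes, 17 of 25 fell while 2 rose (the same adjusted over the list alone), among them the giant protein Ttn (-0.89 ± 0.08). Of 24 potassium and sodium channel genes 18 fell and 2 rose by both adjustments, with the inward rectifier Kcnj3 at -1.76 ± 0.06. Of 25 calcium handling genes 12 fell and 5 rose (the same adjusted over the list alone). These 6 lists had an adjusted p of 0.34 to 0.46 with an estimated correlation. Endothelial markers, by contrast, gave 7 rises and 2 falls among 20 (the same adjusted over the list alone; adjusted p = 0.47 preset and 0.91 with an estimated correlation).

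In all, 4576 genes rose and 4255 fell in wild type, 1996 and 924 of them at least 2-fold. The wild-type TAC libraries had TMM factors of 1.13 to 1.21 against 0.910 to 0.988 in all others. Without these factors the median of all genes moved by 0.33 in this comparison and 8466 genes rose against 1891 that fell, so changes here are relative to that shift. List means moved with it, from -0.34 to -0.01 for calcium handling, -0.45 to -0.12 for sarcomere genes, -0.72 to -0.39 for channels, -0.79 to -0.46 for the respiratory chain, -0.88 to -0.55 for the citrate cycle list and 0.07 to 0.40 for endothelial markers. Wild-type TAC 2 lay apart from the other 2 libraries of its group, at 96.6 against 65.7 and 75.2 on the first principal component (43.5% of variance), and without it 7958 genes were called.

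**Figure D2:**
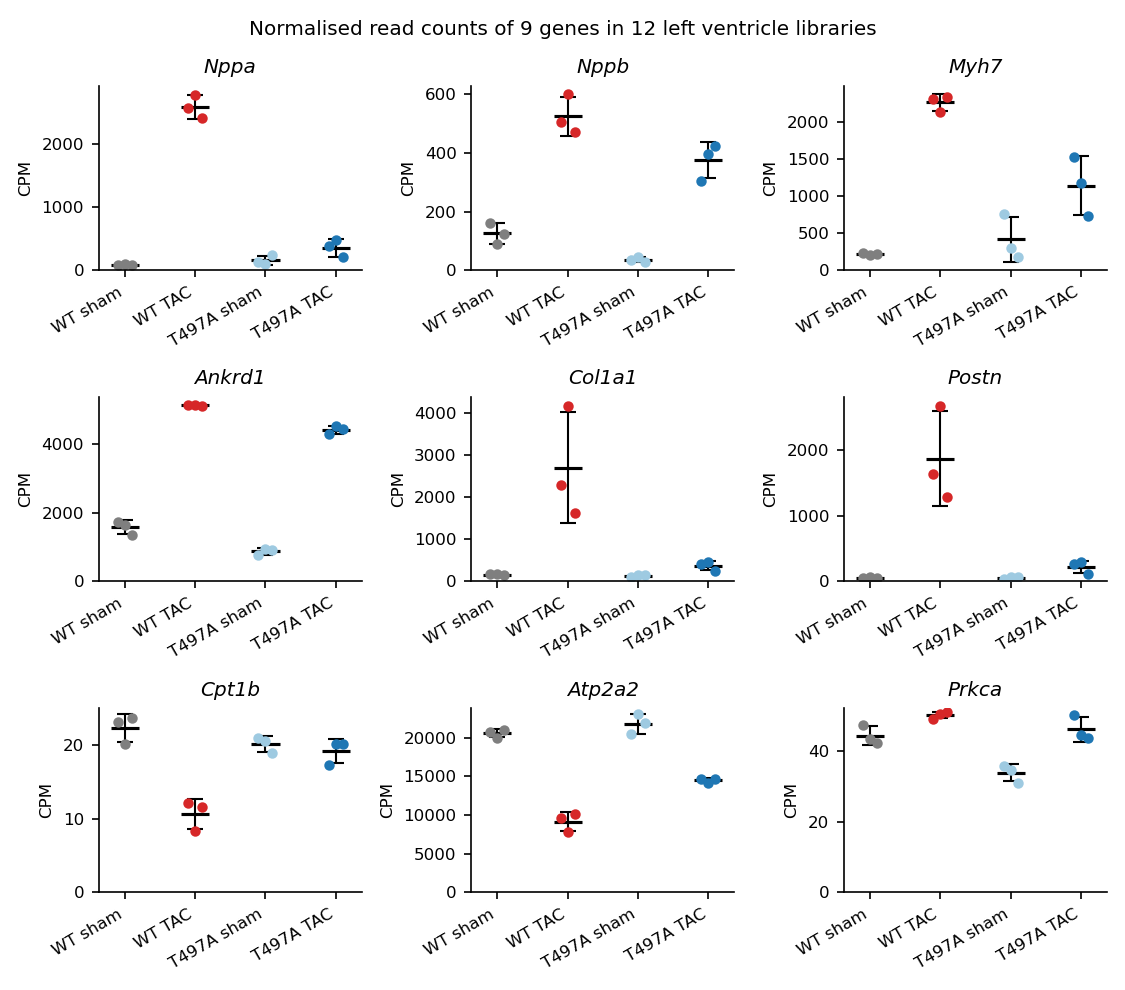
Normalised read counts (CPM, y axes from 0) of 9 genes in each of the 12 libraries by labelled group, with the mean and SD of 3 libraries in black. Col1a1 and Postn are highest in wild-type TAC, Nppb and Ankrd1 are high in both TAC groups, and Cpt1b is lowest in wild-type TAC.

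In the groups labelled T497A, Nppb and Ankrd1 were much higher after TAC than after sham, with a smaller set of matrix and metabolic changes. These 2 groups also differ in Y-linked transcripts and in the 104 autosomal transcripts above. T497A TAC against wild-type sham called 1773 genes, against 4315 here, and Nppb stood at 90.4 to 162 CPM in wild-type sham, above its T497A sham level. Nppb rose from 36.0 ± 8.66 to 375 ± 62.5 CPM (SD, n = 3; log2 fold change 3.38 ± 0.26, adjusted p = 2.6e-05), Ankrd1 rose (2.35 ± 0.10) and so did Acta1 (2.73 ± 0.34). Col3a1 (2.08 ± 0.32) and Postn (2.02 ± 0.42) rose, whereas Ppargc1a, a coactivator of mitochondrial gene expression (-1.17 ± 0.14), Atp2a2 (-0.59 ± 0.10) and Ryr2 (-0.39 ± 0.07) fell. Not called were Myh7 (1.46 ± 0.48, adjusted p = 0.058), the matricellular growth factor Ccn2 (0.41 ± 0.30, adjusted p = 0.38), Pln (-0.30 ± 0.11, adjusted p = 0.066) and Cpt1b (-0.07 ± 0.12, adjusted p = 0.72). Calls that left-out libraries ended were those of Nppa (1.19 ± 0.36, adjusted p = 0.043; 0.0024 to 0.18 over its alternatives), Col1a1 (1.51 ± 0.36, adjusted p = 0.017; 0.00017 to 0.060) and Myh6 (-0.37 ± 0.10, adjusted p = 0.015; 9.3e-05 to 0.065). For Nppa, the adjusted p was 0.13 without T497A sham 1, 0.11 without T497A sham 2, 0.11 without T497A TAC 1 and 0.14 without T497A TAC 2. It was 0.062 to 0.067 without any single wild-type library. Nppa is also an atrial marker, and T497A sham 3, the library highest for the atrial Myl7, had the highest Nppa of its group, 241 against 124 and 103 CPM. Without that library the log2 fold change of Nppa was 1.65. For Col1a1 the adjusted p was 0.060, 0.052 and 0.058, and for Myh6 0.051, 0.054 and 0.065, without T497A sham 1, T497A TAC 1 and T497A TAC 2 in turn.

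By count, cell cycle genes rose with TAC in T497A about as widely as in wild type: 31 of 33 rose and 1 fell (32 and 1 adjusted over the list alone), with Cdk1 at 2.91 ± 0.22 and the spindle midzone protein Prc1 at 2.80 ± 0.24. Against wild type, however, the list averaged -0.51 in T497A after sham and -0.64 after TAC. Immediate early genes, which tissue handling also raises, rose for 16 of 27 and fell for 0 (18 and 1 adjusted over the list alone), among them Egr1 (1.93 ± 0.11), Jun (1.23 ± 0.08) and Btg2 (1.96 ± 0.16). Matrix genes rose for 28 of 49 (34 adjusted over the list alone), with Col4a1 at 1.36 ± 0.09 and fibrillin Fbn1 at 2.14 ± 0.20. Fatty acid oxidation genes fell for 19 of 40 and rose for 1 (22 and 1 adjusted over the list alone). Among those that fell were the transcription factors Ppara (-0.71 ± 0.11) and Esrrb (-0.69 ± 0.10). Respiratory chain genes fell for 20 of 54 (26 adjusted over the list alone), with Sdhc (-0.50 ± 0.08) and Cox7a1 (-0.50 ± 0.09) as examples. Ribosomal protein genes fell for 20 of 50 and rose for 1 (22 and 1 adjusted over the list alone). Endoplasmic reticulum stress genes fell for 10 of 28 and rose for 4 (15 and 5 adjusted over the list alone), with the chaperone Hspa5 at -0.72 ± 0.08 and Herpud1 at -1.41 ± 0.10. With an estimated correlation these 7 lists had an adjusted p of 0.18 to 0.58. Several genes named here already differed between the sham groups, so their change with TAC starts from a shifted level. Prc1 (-0.99), Egr1 (-1.13), Btg2 (-0.64), Fbn1 (-0.80) and Col4a1 (-0.45) were lower in T497A sham than in wild-type sham. Ppara (0.47) and Herpud1 (0.74) were higher there.

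Markers of other tissue differed too. Of 11 atrial markers 7 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.49 with an estimated correlation). The atrial light chain Myl7 stood at 133 ± 111 CPM in T497A sham, with 261 in T497A sham 3, against 10.7 ± 1.85 in T497A TAC. Myl7 lost its call without T497A sham 3 (adjusted p = 0.080; 0.00013 to 0.087 over its alternatives). Mitochondrially encoded transcripts had a mean of 0.30 over 13 members (adjusted p = 0.12 preset and 0.73 with an estimated correlation), and mt-Nd5 was not called (0.36 ± 0.15, adjusted p = 0.093). Mitochondrial genes took 16.8 ± 0.692% of counts in T497A sham (SD, n = 3) and 19.2 to 19.8% in T497A TAC. In all, 2290 genes rose and 2025 fell, 602 and 384 of them at least 2-fold, and 2840 were called without T497A TAC 2.

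Genes called in the same direction with TAC under both labels numbered 1513 up, against 592 for independent lists of these sizes, and 1164 down, against 487. In addition, 224 and 220 were called in opposite directions, against 524 and 551. The pairs of comparisons share no library. A Deming slope of the T497A response on the wild-type response, across all 17699 genes, was 0.205 with a jackknife standard error of 0.188 over the 12 libraries, and it was 0.0848 without T497A TAC 2. The slope reflects weak agreement between the responses as well as their size: Pearson r across genes was 0.125, the signs matched for 64.6% of genes, and the SD of the log2 fold changes was 1.05 in wild type and 0.785 in T497A. The overlap was 2677 genes, and 1771 without T497A TAC 2.

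**Figure D3:**
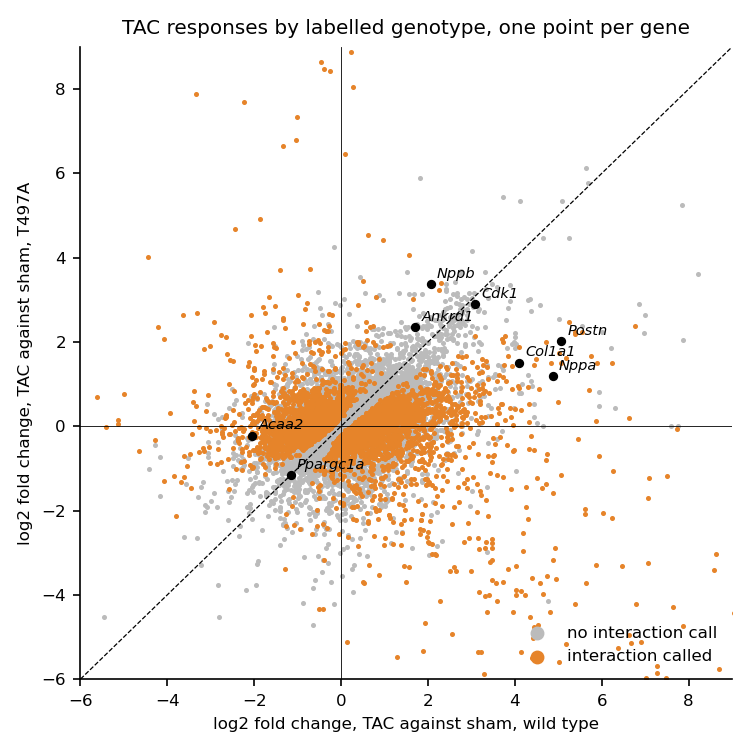
Log2 fold change with TAC of each tested gene in wild type (x axis) and T497A (y axis), with genes called for a different response in orange and a dashed line of equal response; axes run from -6 to 9 and genes beyond are not shown. Postn lies at 5.06 in wild type and 2.02 in T497A, and Cdk1 at 3.08 and 2.91.

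The comparison of the genotypes after sham, which asks what the mutation does without pressure overload, called fewer genes. Nppb (-1.80 ± 0.24, adjusted p = 0.0033) and Ankrd1 (-0.86 ± 0.10, adjusted p = 0.00019) were lower in T497A, at 36.0 ± 8.66 against 125 ± 35.8 CPM and 867 ± 96.0 against 1575 ± 207 CPM (SD, n = 3). The receptor kinase Grk5 (0.63 ± 0.07), the endothelin receptor Ednra (0.86 ± 0.13), the glutathione transferase Gsta3 (1.61 ± 0.16) and the stress protein gene Herpud1 (0.74 ± 0.10) were higher. The immediate early gene Egr1 (-1.13 ± 0.11) and the endothelial adhesion molecule Sele (-1.27 ± 0.20) were lower. Sex-linked transcripts were among the largest differences, with Ddx3y at -8.67 ± 0.19 and Xist at 8.14 ± 0.26, and so was Gpr179 (6.19 ± 0.64), which went from 0.138 ± 0.0657 to 10.3 ± 2.9 CPM. Of the 16 genes fixed for every comparison the other 14 were not called, among them Myh7 (0.91 ± 0.47, adjusted p = 0.34), Postn (-0.03 ± 0.41, adjusted p = 0.98), Atp2a2 (0.08 ± 0.10, adjusted p = 0.71) and Cpt1b (-0.15 ± 0.12, adjusted p = 0.54).

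Few members of the ribosomal, cell cycle and matrix lists were called after sham. Other lists held called members in both directions, such as the mural markers Colec11 (-1.06 ± 0.22) and Lmod1 (0.64 ± 0.17). The same held for the endothelial markers Kdr (-0.53 ± 0.12) and Flt1 (0.46 ± 0.09). Ribosomal protein genes gave 2 higher and 0 lower of 50 (7 and 1 adjusted over the list alone), including Rps6 (0.29 ± 0.05). Cell cycle genes gave 0 higher and 2 lower of 33 (1 and 9 adjusted over the list alone; median -0.56). Matrix genes gave 1 higher, Adamtsl2 (1.11 ± 0.19), and 3 lower of 49 (1 and 4 adjusted over the list alone), with a mean of 0.02 and a median of 0.02 but a test pointing down (adjusted p = 0.60 preset and 0.97 with an estimated correlation). With an estimated correlation the ribosomal list had an adjusted p of 0.72 and the cell cycle list of 0.72. In all, 529 genes were higher and 495 lower, and without TMM factors 730 and 375. The number called was 546, 505 and 537 without wild-type sham 1, 2 and 3, 679 without T497A sham 1, 592 without T497A sham 3 and 1607 without wild-type TAC 2, against 1024 with all libraries.

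After TAC, which asks whether the mutation changes the overloaded ventricle, matrix transcripts were lower and mitochondrial and fatty acid oxidation transcripts higher in T497A. Postn stood at 222 ± 92.2 against 1865 ± 724 CPM in wild type (SD, n = 3; -3.07 ± 0.43, adjusted p = 0.00067), Col1a1 at 370.0 ± 111 against 2695 ± 1319 CPM (-2.86 ± 0.38) and Nppa at 355 ± 138 against 2596 ± 189 CPM (-2.87 ± 0.38). Col3a1 (-2.34 ± 0.32) and Ccn2 (-1.38 ± 0.31) were lower, while Cpt1b (0.85 ± 0.12), Myh6 (0.83 ± 0.10), Pln (0.76 ± 0.11), Atp2a2 (0.67 ± 0.10) and Ryr2 (0.46 ± 0.07) were higher. Nppb (-0.48 ± 0.23, adjusted p = 0.14), Ankrd1 (-0.21 ± 0.10, adjusted p = 0.11), Acta1 (-0.65 ± 0.32, adjusted p = 0.15) and Myh7 (-0.99 ± 0.47, adjusted p = 0.14) were not called. Both groups carry Y-linked transcripts, and this comparison called 6458 genes without the T497A sham libraries in the fit against 6321 with them.

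By list, 47 of 49 matrix genes were lower and 0 higher in T497A after TAC (49 and 0 adjusted over the list alone; median -1.97), with Col4a1 at -0.98 ± 0.09 and Col6a3 at -1.32 ± 0.12. Fibroblast markers were lower for 15 of 19 and higher for 2 (15 and 3 adjusted over the list alone). Macrophage markers were lower for 14 of 20 and higher for 1 (the same adjusted over the list alone), among them Trem2 (-1.74 ± 0.23). Cell cycle genes were lower for 19 of 33 and higher for 1 (24 and 1 adjusted over the list alone). Higher were 38 of 40 fatty acid oxidation genes (38 adjusted over the list alone), 53 of 54 respiratory chain genes (54, likewise), 37 of 39 of the citrate cycle list (37, likewise, with 2 lower) and 10 of 13 mitochondrially encoded transcripts (13, likewise), with Acaa2 at 1.61 ± 0.09, Sdha at 0.89 ± 0.08 and mt-Nd5 at 1.03 ± 0.15. Adult sarcomere genes were higher for 19 of 25 and lower for 2 (20 and 2 adjusted over the list alone), with Ttn at 0.82 ± 0.08. Calcium handling genes were higher for 12 of 25 and lower for 4 (the same adjusted over the list alone), with a mean of 0.19 that turns to -0.06 without TMM factors. These 10 lists had an adjusted p of 0.31 to 0.56 with an estimated correlation. Glycolysis genes were split, with 10 of 25 higher and 7 lower (11 and 7 adjusted over the list alone; adjusted p = 0.93 with an estimated correlation), Pfkp at -0.96 ± 0.08, and a mean of 0.07 that turns to -0.18 without TMM factors. In all, 3156 genes were higher and 3165 lower with TMM factors, and 1458 and 6874 without them, where the median of all genes moved by -0.25. List means then moved from 0.46 to 0.21 for sarcomere genes, 0.61 to 0.36 for the respiratory chain and 0.67 to 0.42 for the citrate cycle list.

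The interaction tests whether the response to TAC itself differed between the labels, and called 5218 genes. Of these, 4252 had the smaller response in T497A (81.5%), and the estimates of the 2 responses had opposite signs for 2505. The difference of the responses, T497A minus wild type, was -3.69 ± 0.52, adjusted p = 0.00099 for Nppa, -3.04 ± 0.58, adjusted p = 0.0049 for Postn, -2.58 ± 0.51 for Col1a1 and -2.42 ± 0.43 for Ccn2, which had risen in wild type. For Nppa it was -3.23 without T497A sham 3. It was 1.00 ± 0.17 for Cpt1b, 0.75 ± 0.14 for Myh6, 0.72 ± 0.16 for Pln and 0.58 ± 0.14 for Atp2a2, which had fallen there. Nppb (1.31 ± 0.34) and Ankrd1 (0.65 ± 0.14) went the other way, with the larger rise in T497A, from the lower sham level given above. The interaction was not called for Prkca (0.27 ± 0.10, adjusted p = 0.061; -0.03 without TMM factors), Acta1 (-0.42 ± 0.45, adjusted p = 0.53), Myh7 (-1.90 ± 0.67, adjusted p = 0.065) or Ppargc1a (-0.01 ± 0.20, adjusted p = 0.98). For Col3a1 (-1.62 ± 0.43, adjusted p = 0.021) the call ended without wild-type sham 3 (adjusted p = 0.050) or wild-type TAC 2 (0.053; 0.0011 to 0.053 over its alternatives).

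Among the lists, the interaction was negative for 44 and positive for 0 of 49 matrix genes (47 and 0 adjusted over the list alone), with Sparc at -1.69 ± 0.21. It was negative for 15 and positive for 2 of 19 fibroblast markers (16 and 3, likewise). It was positive for 33 of 40 fatty acid oxidation genes (35 adjusted over the list alone), 50 of 54 respiratory chain genes (52, likewise), 37 of 39 of the citrate cycle list (37, likewise), 10 of 13 mitochondrially encoded transcripts (11, likewise) and 18 of 25 sarcomere genes (19, likewise), with Acaa2 at 1.82 ± 0.13, Bckdha at 1.39 ± 0.13 and Ttn at 0.89 ± 0.11. For these 7 lists the adjusted p was 0.36 to 0.42 with an estimated correlation. Only 1 of 33 cell cycle genes had a called interaction (0 adjusted over the list alone; adjusted p = 0.41 preset and 0.96 with an estimated correlation). Without TMM factors 1175 genes had a positive and 5694 a negative interaction, against 2700 and 2518 with them, and the median of all genes moved by -0.30. List means then moved from 0.54 to 0.24 for sarcomere genes, 0.56 to 0.27 for the respiratory chain, 0.71 to 0.41 for the citrate cycle list and -0.14 to -0.44 for cell cycle genes.

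**Figure D4:**
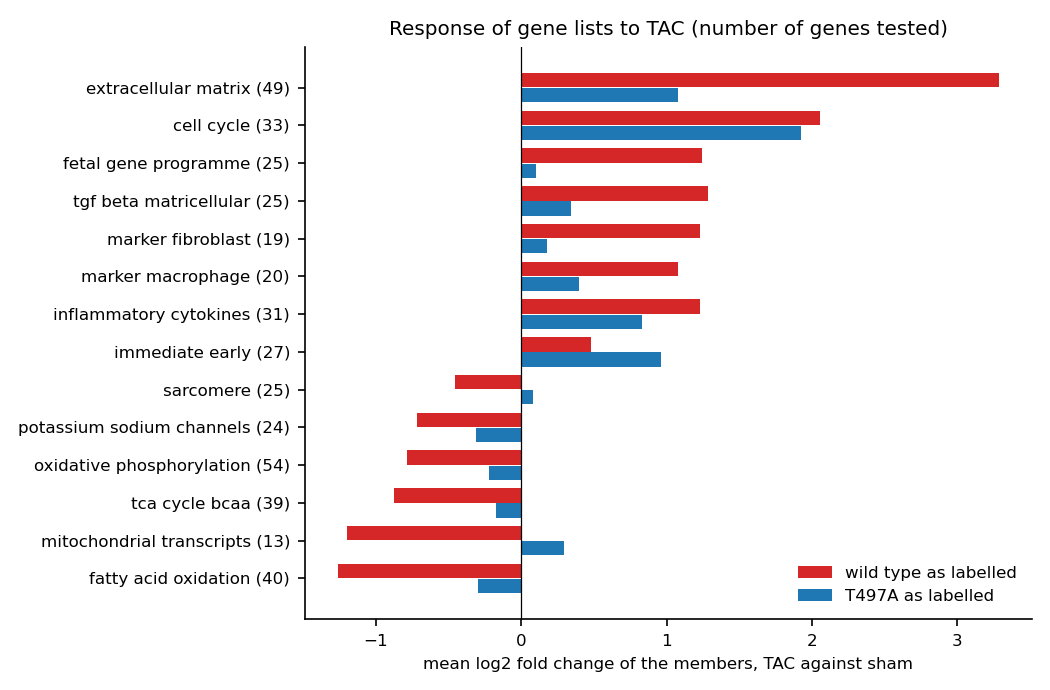
Mean log2 fold change with TAC (x axis) over the tested members of 14 gene lists, with the number of members in parentheses, in wild type (red) and T497A (blue) as labelled. Matrix genes averaged 3.29 in wild type and 1.08 in T497A, cell cycle genes 2.06 and 1.92, and mitochondrially encoded transcripts -1.20 and 0.30.

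A score per library, the mean log2 CPM over the members of a list, gave a test that uses the libraries as its units (2-sided exact permutation of genotype within surgery, 400 reassignments, smallest p 0.005). After adjustment over 33 lists 7 differed in their response, each with an adjusted p of 0.047. The difference, T497A minus wild type, was 1.54 for mitochondrially encoded transcripts, 0.72 for the citrate cycle list, 0.54 for sarcomere genes, -1.03 for fibroblast markers, -1.79 for atrial markers, -0.46 for endoplasmic reticulum stress genes and -0.13 for ribosomal protein genes. Without TMM factors 11 lists were called, and these differences were 1.26, 0.42, 0.24, -1.33, -2.09, -0.76 and -0.43 in the same order. The citrate cycle list (adjusted p = 0.12) and the sarcomere genes (adjusted p = 0.055) then lost their call. With the factors, the difference was -2.21 for matrix genes (adjusted p = 0.11, not called) and 0.97 for fatty acid oxidation genes (adjusted p = 0.083, not called). The sham libraries are reassigned too, so p also depends on how the sham difference ranks, however large the TAC difference is. For matrix genes the mean sham difference was 0.02 and unadjusted p 0.05, so the missing call does not show an equal response. The called lists differed after sham in the opposite direction to after TAC. For mitochondrially encoded transcripts the means were -0.37 and 1.13, and for ribosomal protein genes 0.10 and -0.03. No list was called without wild-type sham 1, wild-type sham 3 or T497A sham 3, where the smallest adjusted p was 0.055. With so few reassignments p moves in coarse steps, so a small change can carry all lists from 0.047 to 0.055.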

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

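The interaction, the library score of the lists and leaving out each library were planned. Apart from these and the tests of a strain variant, of a heterozygous background and of other splits of the samples, the tests in this part were chosen only after the result was seen. What follows was picked out because the response to TAC differed between the genotypes by a test of the interaction. Groups hold 3 libraries, so no formal test for a single distant library was run within a group, and each library was left out in turn instead. The interaction was called for 5218 of 17699 genes (29.5%), of which 4252 had the smaller response in T497A. Of the 312 named genes, some of which were chosen by their call in the interaction, it was called for 222, and 167 of these lay closer to 0 in T497A.

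Of the fixed genes, the difference in log2 response (T497A minus wild type) was -3.69 for Nppa, -3.04 for Postn, -2.58 for Col1a1, -2.42 for Ccn2, -1.62 for Col3a1, 1.66 for Ppp1r1a, 1.31 for Nppb, 1.00 for Cpt1b, 0.75 for Myh6, 0.72 for Pln, 0.65 for Ankrd1, 0.58 for Atp2a2 and 0.31 for Ryr2. The call of Ryr2 was lost in 11 of 20 alternatives. The largest negative differences were Gpr179 -10.63, Ifi202b -8.43, Eno1b -8.31, Xist -8.30, P4ha3 -5.77, Ptprv -5.75 and Pianp -5.71. Adgrf3 gave -15.97, a fitted value that is no bound, since its counts were near 0 in wild-type sham and T497A TAC and its SD exceeded its mean in wild-type TAC (10.2 ± 12.1 CPM, n = 3) and T497A sham (17.4 ± 29.4 CPM). Large positive differences were Uty 9.10, Ddx3y 8.88, Kdm5d 8.68, Eif2s3y 8.65, Hba-a2 8.36, Rab6b 4.76 and Drc3 4.70. Ifi202b, Eno1b and Hba-a2 have near-identical copies, and how reads were divided among these is not given, so their values are uncertain. By library score, lists differed for mitochondrially encoded transcripts (1.54), the citrate cycle list (0.72), sarcomere genes (0.54), ribosomal protein genes (-0.13), endoplasmic reticulum stress genes (-0.46), fibroblast markers (-1.03) and atrial markers (-1.79), of which the citrate cycle list and the sarcomere genes were not called without TMM factors. The atrial list was written as a check on dissection. Its member Myl7 ran from 6.64 to 84.5 CPM within wild-type sham and from 63.6 to 261 CPM within T497A sham. Whether atrial tissue in the samples gave that difference was not tested.

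The 104 autosomal transcripts that differed at least 4-fold between the sham groups mostly differed the other way between the TAC groups: a lasting effect of the labelled genotype would give the same sign in both, and 8.65% kept it. The sex of the T497A sham mice would give the wild-type sham level in wild-type TAC, which carries Y-linked transcripts, and the median position there was 0.685. A strain variant against the reference may underlie many of them, since 27.9% were processed pseudogenes, whose mapping depends on single bases, against 3.78% of all autosomal genes tested (odds ratio 10.3, Fisher exact p = 9.78e-18). Without the 4-fold limit no such excess was seen: 36 of 682 processed pseudogenes were called after sham, against 1024 of all 17699 genes. The test did not match genes on their level. Open is an exchange of genotype labels in one surgery, for which the 10 transcripts within 10 Mb of Prkca lay at 0.831 of the sham difference in wild-type TAC and at 0.0498 in T497A TAC. Of the 104, 31.7% lay on chromosome 11, which carries Prkca, against 8.25% of the autosomal genes tested (odds ratio 5.27, Fisher exact p = 5.27e-12). This argues against a background difference spread evenly over the genome as the whole cause. Mice with another background around Prkca could give the same values for the transcripts near it, and counts per gene do not show the mutation. The rest of the 104 lay on other chromosomes, which a background around Prkca alone does not cover. A background that differs around Prkca and also elsewhere cannot be told apart from an exchange.

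T497A TAC 2 carried transcripts of this kind at a low level. Taken were 51 that were higher in T497A sham and stood, by a set margin, higher in wild-type TAC than in the mean of the other T497A TAC libraries. The median in T497A TAC 2 was 0.0806 of the distance from that mean to the wild-type TAC level, with 41 of the 51 above both other libraries of its group. RNA or reads from a T497A sham library would bring Xist, whose ratio to the other transcripts was -0.00889. A heterozygous background would put many near the middle, and 1.96% lay over 0.3. Admixture from a wild-type TAC library could give a steady share, and the interquartile range was 0.119, between the bounds of 0.1 and 0.25 set for that test, so it stays open.

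The response to TAC was smaller in the libraries labelled T497A. An error of scaling adds 1 constant to every gene and cannot change the slope of the T497A response on the wild-type response. That slope was 0.205 (jackknife standard error 0.188), and 0.206 without TMM factors. It reflects weak agreement (Pearson r 0.125) as well as size. The SD of the log2 fold changes, which a constant also leaves as it is, was 1.05 in wild type and 0.785 in T497A, and 1.05 and 0.784 without TMM factors. These values argue against scaling as the whole cause, although scaling moves the split of calls by direction. The sex of the T497A sham mice does not enter the comparison after TAC, where 6321 genes were called. A strain background or exchanged genotype labels may be part of it: 0 of the 3 wild-type TAC libraries lay below 0.5 for the transcripts above, and an exchange of genotype labels within 1 surgery would turn the interaction (5218 genes) into the average effect of genotype (3822 genes) and the reverse. An exchange within TAC would make T497A TAC against wild-type sham (1773 genes called) the wild-type response. The mutant response would then be wild-type TAC against T497A sham (8891 genes called), the larger by count. An exchange within sham would leave the smaller count with T497A. A biological effect of the mutation stays open as well, and the design does not part it from a strain background or an exchange of labels. No measure of the pressure reached was used here, so a difference in load between the TAC groups was not tested.

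For each comparison of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real and highest other counts were 8831 and 0 for TAC in wild type, 4315 and 0 for TAC in T497A, 1024 and 0 for genotype after sham, 6321 and 0 for genotype after TAC, 1773 and 0 for T497A TAC against wild-type sham, and 8891 and 1 for wild-type TAC against T497A sham. For the interaction 1 of 100 splits, the real one, reached 5218, with 3822 as the highest other. For surgery averaged over genotypes 1 of 100 reached 8558, with 5660 as the highest other. For genotype averaged over surgeries 2 of 100 reached 3822. The highest other there was 5218, from the split that exchanges genotypes in 1 surgery. For the slope, distance from 1 was taken on a log scale, on which a slope and its reciprocal lie equally far from 1. There 1 of 100, the real one at 0.205, lay as far from 1, with 0.347 or its reciprocal as the next furthest. These shares lie under 0.05 for a random division of the libraries. They say no more than that, since most other splits mix groups that differ, which widens the spread within each side. A difference in sex, background or labels would set the real groups apart in the same way. Of 98 further splits for the interaction 15 made calls, up to 3307, and the cause was not tested.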

How the results depend on the processing

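The fits without the T497A sham group, with autosomal protein-coding genes only, without TMM factors and for the 4 further contrasts were chosen after seeing the data. Over all alternatives the number of genes called stayed within 1.5 times for TAC in wild type (7922 to 8994 with a library left out), genotype after TAC (5266 to 6491) and the interaction (4394 to 5283), and also for the averages of surgery and of genotype and for wild-type TAC against T497A sham. For the results that follow it did not, and the cause was not tested. TAC in T497A called 2840 genes without T497A TAC 2 (2840 to 5152). Genotype after sham called 1625 with the DESeq2 test and 505 to 1607 with a library left out (546, 505 and 537 without wild-type sham 1, 2 and 3, 679 and 592 without T497A sham 1 and 3, 1607 without wild-type TAC 2). T497A TAC against wild-type sham called 3971 with limma-voom, 2992 with only the 2 groups compared, and 623 to 2812 with a library left out (778, 924 and 903 without wild-type sham 1, 2 and 3, 2812 without wild-type TAC 2, 623 and 1075 without T497A TAC 2 and 3). The overlap of 2677 genes was 1771 to 3008 with a library left out (1771 without T497A TAC 2) and 1451 at an adjusted p of 0.01. The slope of 0.205 was 0.0848 to 0.277, with 0.0848 without T497A TAC 2 and 0.277 without T497A sham 1.

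Lists called by camera with a preset correlation numbered 17, 20, 7, 16 and 17 in the 5 comparisons in the order of the report, and 0 in each with an estimated correlation. Fry called 21, 18, 3, 18 and 19. The 7 lists of the library score test were 11 without TMM factors and 0 to 8 with a library left out, and 0 without wild-type sham 1, wild-type sham 3 or T497A sham 3, where the smallest adjusted p of this permutation test was 0.055. Without TMM factors 3 named genes turned from a called fall to a rise with TAC in wild type, Cidea (0.013), Bpgm (0.034) and Rps25 (0.060), as all libraries of wild-type TAC have a factor over 1. Named genes kept their side of the threshold in every alternative for 141 of 152, 115 of 143, 43 of 98, 125 of 150 and 121 of 145 in the 5 comparisons.

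The groups share replicate numbers, and the pairing check found no pairs: over 18 pairs with the same number, deviations from the group means correlated at -0.113 to 0.0742, with 0 over 0.1, and 3 of 18 correlated best with their own number. With a replicate block the calls were 8579, 4021, 862, 5994 and 4921 in the 5 comparisons, 8293 and 3548 for the averages of surgery and genotype, 1581 and 8624 for T497A TAC against wild-type sham and wild-type TAC against T497A sham, with 17, 20, 7, 16 and 17 lists, a slope of 0.201 and an overlap of 2538. At this depth and number of libraries, 95.5% of simulated 4-fold interactions but 28.4% of 1.5-fold ones were recovered. The simulation changed 200 genes and made 131 interaction calls, against 5218 in the data, so its threshold on p was stricter. Its shares therefore do not give the recovery in the data, although small differences in response may be missed.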

Other observations

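Genes of 2 further lists, growth factors and inflammatory cytokines, were called with TAC. Of 25 genes of the TGF-beta and matricellular list 20 rose and 1 fell in wild type (20 and 1 adjusted over the list alone), and 8 rose and 2 fell in T497A (9 and 2, likewise). Gdf15, a stress cytokine, rose by 3.17 log2 units in wild type and 1.26 in T497A, and Tgfb2 by 1.93 and 0.84. Tgfb1 rose by 0.74 and 0.85. After TAC, 14 of these genes were lower and 1 higher in T497A (17 and 1, likewise), among them Gdf15 (-1.53 ± 0.16). Of 31 cytokine genes 17 rose and 1 fell in wild type (18 and 1, likewise), and 12 rose and 1 fell in T497A (13 and 3, likewise), with the monocyte attractant Ccl2 at 2.32 ± 0.37 in T497A. With an estimated correlation the adjusted p of these 2 lists was 0.34 in wild type, 0.37 to 0.58 in T497A and 0.37 to 0.70 between the TAC groups. Without TMM factors the mean of the cytokine list between the TAC groups moved from -0.45 to -0.71.

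Clock genes, a check on the hour of tissue collection, fell for 10 of 20 and rose for 1 with TAC in wild type (10 and 2 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation), and their mean of -0.37 moved to -0.04 without TMM factors. In T497A they fell for 4 and rose for 2 (4 and 3 adjusted over the list alone), with a mean of 0.03 and a median of 0.14 against a camera test that pointed down (adjusted p = 1 with an estimated correlation).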
